A study of Homo sapiens with 13 samples.

How the data were processed

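Primary adult human Schwann cells from spinal nerve, bought from a supplier, were grown to 90% confluence and treated for 48 h, and biotin-labelled cRNA was made from 100 ng of total RNA, per the labels' protocols. The arrays were Affymetrix Human Genome U133A 2.0. The deposited values are log2 expression values per probe set, between 2.53 and 14.41; the submitters' processing notes name affy and RMA, and versions and settings are not given in the sources used here. RMA summarises probes and normalizes between arrays, so a shift shared by most genes would not be seen. A 13th column, of a kidney RNA standard, holds no values and was not used (1 column).

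Of 15550 probe sets, 13188 had 1 gene symbol in the platform annotation, 702 several and 1660 none here; genes were named only from the first kind. Symbols were set against a RefSeq gene table of assembly GRCh38.p14 through the gene identifier, which changed 0 symbols and left 11 identifiers unmatched. Probe sets of XIST, TSIX and Y-linked genes (22) were left out. The probe set with the highest mean over the 12 arrays stood for each of the 9052 genes, 2697 of which had more than 1. Levels of different probe sets were not compared as amounts.

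Group means of the 4 groups (3 arrays each) were fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3) with no block, and 7 contrasts were taken: each melanoma medium against control, the mean of the 3 against control, and each pair of media. Tests were two-sided and p-values were adjusted by Benjamini-Hochberg over the 9052 genes, with 0.05 as the threshold. "Rose" and "fell" stand for genes that passed. Errors are standard errors of the log2 change unless named otherwise. Of 38 gene lists chosen before the data were examined, the 37 with at least 5 measured genes were tested with camera (preset correlation 0.01), adjusted over the 37 lists, and again with an estimated correlation and with fry. Called lists are described in each comparison.

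Named genes were chosen by a rule fixed before the data were examined. They are the 10 largest rises and 10 largest falls among passing genes whose arrays did not overlap (for the mean of the 3 media, whose 3 medium means lay on the same side), or the 4 largest between media. Where fewer than 5 genes passed, the 5 with the smallest p were taken. Up to 4 members with the smallest p were named from each list, together with S100B, SOX10, NGFR, MBP, JUN, GFAP and GAP43; other Schwann cell genes of the rule were not analysed here. METTL5 and further list members named in the text were chosen after their values were seen.

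On data simulated for the 526-mel against control comparison (9052 genes, 200 changed per run, 10 runs), the fit recovered 43.2% of changes of 0.3 on the log2 scale, 98% of 0.5 and 100% of 1, and 5.65% of its calls were false. A list shifted by 0.2 was called in 10 of 10 runs, and 1 other list was called. Each gene was drawn independently, so these runs do not give the rate of false list calls for genes that vary together. With 200 changed genes the adjusted threshold is also easier to reach than in the real comparisons, where far fewer genes passed. The shares recovered therefore overstate what could be found there. With 624-mel medium, for example, CYTIP at 0.52 did not pass (limma adjusted p = 0.0997). The alternatives were quantile normalization, median centring, leaving out the dimmest genes (a share of 0.333), the mean of all probe sets of a gene, every probe set by itself, an intensity trend with robust hyperparameters, array weights (statmod 1.5.0), a fit of only the groups compared, the replicate number as a block and leaving out each array in turn.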

Results

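Gene expression was measured in primary human Schwann cells, the glia of peripheral nerve, after 48 h of culture with 20% (v/v) of either plain RPMI-1640 (control medium) or medium conditioned by a melanoma cell line. The 3 lines were 526-mel, 397-mel and 624-mel, and each of the 4 groups held 3 arrays. The Affymetrix U133A 2.0 arrays gave log2 values for 15550 probe sets, of which 1 per gene was tested for 9052 genes. Array medians lay between 5.56 and 5.62, and arrays of the same group correlated across genes at r between 0.996 and 0.998. The number of arrays limits the precision: the median standard error of a log2 change between 2 groups was 0.0899. The labels call the samples biological replicates of cells cultured in triplicate, and whether they come from 1 donor or lot is not known here. The p-values measure the spread between these samples, and not between donors if there was only 1. The control medium was not conditioned by any cells, and each group held 1 medium. In the comparisons with control, an effect of a melanoma line therefore cannot be told apart from conditioning by cells in general or from handling.

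The first question is which genes of the Schwann cells differed from control with conditioned medium of the 3 lines. In the mean of the 3 melanoma media, 9 genes rose and 0 fell. STC2, a secreted glycoprotein induced by cellular stress, rose by 0.61 ± 0.07 on the log2 scale (SE, adjusted p = 2.838e-05), and CYTIP, a scaffold protein that binds cytohesins, rose by 0.61 ± 0.08 (adjusted p = 0.000274). NPTX1, a neuronal pentraxin, rose by 0.43 ± 0.07 (adjusted p = 0.00112) and TMEM156, a membrane protein, by 0.45 ± 0.08 (adjusted p = 0.0144). CYP1B1, a cytochrome P450 of steroid and retinoid metabolism, rose by 0.58 ± 0.11 (adjusted p = 0.0215).

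The interstitial collagenase MMP1 rose by 0.34 ± 0.07, the protease inhibitor TFPI2 by 0.32 ± 0.07 and PAPPA, a protease of IGF-binding proteins, by 0.45 ± 0.09, with adjusted p = 0.034 for MMP1 and PAPPA and 0.0348 for TFPI2. TIPARP, an ADP-ribosyltransferase, rose by 0.33 ± 0.07 (adjusted p = 0.034). The list of matrix proteases and inhibitors, of which MMP1 is a member, was not called (adjusted p = 0.509), with 15 of 21 members at a negative log2 change. In each of these 9 genes the means of the 3 media all lay above the control mean. For 43.24% of all genes the 3 means lay on the same side of it. At an unadjusted p under 0.05 stood 409 genes, 168 higher and 241 lower, against 452.6 expected by chance. The count was 3 without control replicate 2 or 397-mel replicate 3, 4 without control replicate 3 or 397-mel replicate 2, and 5 without control replicate 1, 526-mel replicate 3, or 624-mel replicate 1 or 2. MMP1 also missed the threshold without 397-mel replicate 1 (0.0504, with TFPI2) or 624-mel replicate 3 (0.0546). The count was 2 when the 9 melanoma arrays were fitted as a single group, and 17 with an intensity trend and robust hyperparameters, where CYP1B1 did not pass (adjusted p = 0.664). With the mean of all probe sets of a gene, CYP1B1 (0.148) and PAPPA (0.127) did not pass. After quantile normalization MMP1 (0.281) did not, and with the replicate number as a block TFPI2 (0.0531) did not.

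**Figure D1:**
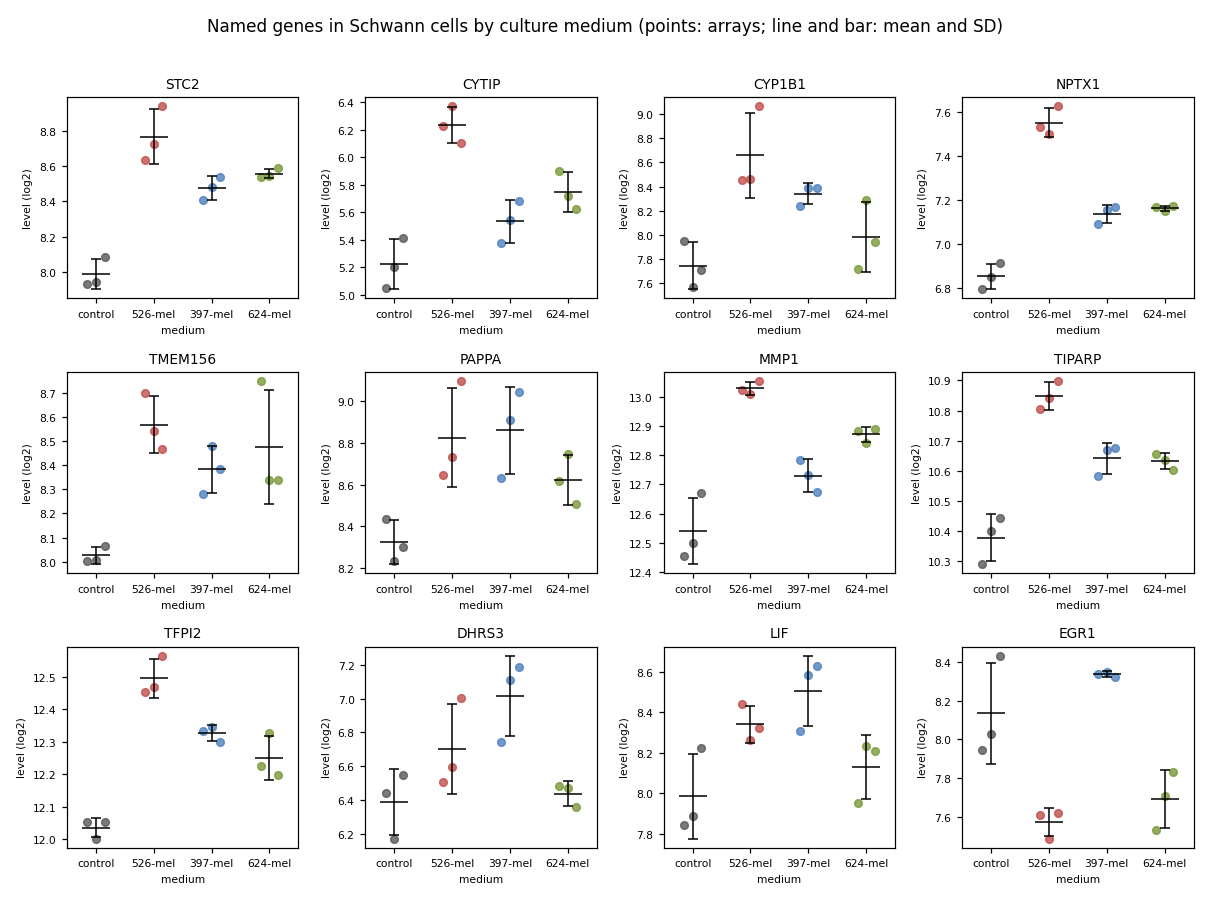
Log2 level (y axis of each panel, own scale, not starting at 0) of 12 named genes on each array, by culture medium (x axis); points are arrays, the horizontal line is the group mean and the bar is 1 SD (n = 3). All 3 arrays of each melanoma medium lie above all 3 control arrays for STC2, whereas EGR1 is at 7.58 with 526-mel medium, 7.69 with 624-mel medium, 8.33 with 397-mel medium and 8.14 in control medium.

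Among the gene lists, 4 of 37 were shifted upward in the mean of the 3 media by camera with a preset correlation of 0.01, and 0 downward. Of the lists called, 3 of 4 were shifted upward without control replicate 1, and 5 of 8 without the dimmest genes. With an estimated correlation 0 lists passed (smallest adjusted p = 0.517), and 22 of 100 groupings of the arrays gave at least 4 lists. In the list of retinoid and steroid response genes (adjusted p = 0.000136; with an estimated correlation, adjusted p = 0.517), 2 of 17 measured members rose, CYP1B1 and TIPARP, both known targets of the aryl hydrocarbon receptor and not of retinoids. The retinoid-responsive members DHRS3 and RARB stood at 0.33 ± 0.10 and 0.20 ± 0.07 without passing over all genes. Adjusted over the list alone, 4 members of this list passed. Without CYP1B1 and TIPARP the list did not pass (adjusted p = 0.0535), and its mean log2 change was 0.0597 against 0.106 with them. Without its retinoid genes it still passed by camera (adjusted p = 0.0239, mean 0.0998). Of the 18 measured TGF-beta targets (adjusted p = 0.000136; with an estimated correlation, adjusted p = 0.517), 14 had a positive log2 change and 0 passed, over all genes or adjusted over the list alone. The members with the smallest p were TGFB2 at 0.21 ± 0.07, INHBA at 0.19 ± 0.07 and SMAD7 at 0.19 ± 0.07.

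The neurotrophic factors were shifted upward (adjusted p = 0.0241; with an estimated correlation, adjusted p = 0.517), with LIF at 0.34 ± 0.09 and FGF2 at 0.25 ± 0.07; 0 of 18 measured members passed over all genes and 2 adjusted over the list alone. In the hypoxia list (adjusted p = 0.0214; with an estimated correlation, adjusted p = 0.6), STC2 was the 1 of 16 measured members that rose, and 1 passed adjusted over the list alone. Without STC2 the hypoxia list had an adjusted p of 0.222. In none of the 7 comparisons did any list pass with an estimated correlation. Without control replicate 2, only the TGF-beta targets stayed past the threshold, and the retinoid and steroid list had an adjusted p of 0.0688. The neurotrophic factors missed it without control replicate 1 (0.175), control replicate 2 (0.0854), 526-mel replicate 3 (0.0587) or 397-mel replicate 1 (0.0552). The hypoxia list missed it without control replicate 2 (0.0854), control replicate 3 (0.0682), 526-mel replicate 3 (0.0689) or 397-mel replicate 3 (0.0835). It also missed it after quantile normalization (0.0778), as the neurotrophic factors did with the mean of all probe sets (0.0659).

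**Figure D2:**
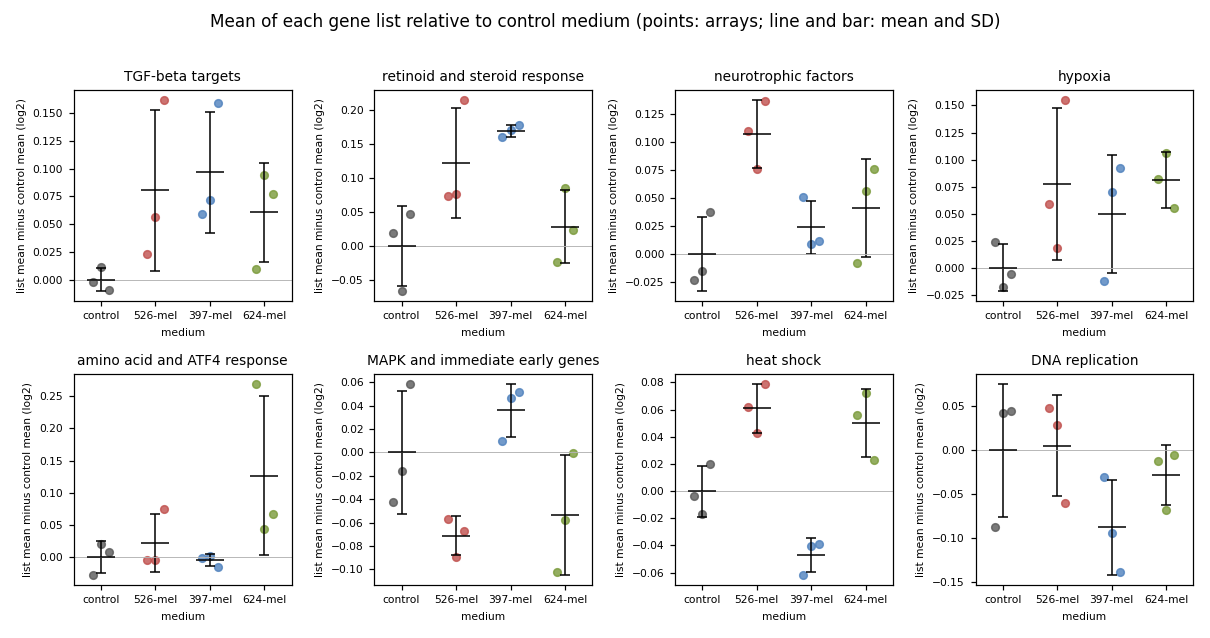
Mean of the measured genes of 8 lists on each array, as the log2 difference from the control mean (y axis, own scale per panel), by culture medium (x axis); points are arrays, the horizontal line is the group mean and the bar is 1 SD (n = 3). For the amino acid and ATF4 list, 624-mel replicate 1 lies at 0.27 and the other 624-mel arrays at 0.043 and 0.067.

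Schwann cell identity genes were measured in the same arrays. S100B, SOX10 and NGFR, which mark the Schwann cell lineage, did not pass in any comparison; against control medium, the mean of the 3 media stood at 0.08 ± 0.09 for S100B, -0.05 ± 0.08 for SOX10 and 0.08 ± 0.09 for NGFR. In control medium their levels were 3.32, 5.08 and 4.15 on a scale that starts at 2.53, and no detection calls were used. GFAP, GAP43 and JUN, which rise in Schwann cells after nerve injury, stood at -0.17 ± 0.07, -0.10 ± 0.07 and -0.08 ± 0.07, and the myelin gene MBP at 0.15 ± 0.07, all with adjusted p of 0.994 or above. Of the other probe sets of a gene, 2 went the other way for GAP43, 2 for MBP and 1 for SOX10. The Schwann cell lineage list had an adjusted p of 0.222 over 12 measured members (with 397-mel medium alone 0.0551, mean -0.0807, 10 of 12 negative, not called), the repair program 0.678 over 17 and the myelin list 0.834 over 13. Their counts of passing members over all genes were 0, 0 and 0 by limma; adjusted over the list alone, 1 member of the repair program passed, LIF at 0.34. Markers of fibroblasts (adjusted p = 0.579), melanocytes and melanoma (0.941), macrophages and leukocytes (0.941), endothelium and pericytes (0.89) and neurons (0.146) were not called in this comparison. For macrophages and leukocytes camera pointed upward while the mean (-0.00332) and median (-0.0214) were negative, and for myelin it pointed downward with a mean of -0.0115 and a median of 0.00016.

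With medium of 526-mel cells 11 genes rose and 1 fell. CYTIP rose by 1.01 ± 0.10 (2.015-fold, adjusted p = 1.412e-06), CYP1B1 by 0.91 ± 0.13 (adjusted p = 0.000501), STC2 by 0.78 ± 0.09 (adjusted p = 5.482e-06) and NPTX1 by 0.70 ± 0.08 (adjusted p = 5.482e-06). TMEM156 rose by 0.54 ± 0.10 (adjusted p = 0.00667) and IL24, a cytokine of the IL-10 family, by 0.51 ± 0.09 (adjusted p = 0.00401). The rises of MMP1, TIPARP, LYPD1 and TFPI2 lay between 0.46 and 0.49, each with adjusted p = 0.00401. METTL5, an RNA methyltransferase, was the last of the 11, at 0.46 (adjusted p = 0.0463), and its call was the least stable. EGR1, an immediate early transcription factor, fell by 0.56 ± 0.10 (adjusted p = 0.00667). All 3 arrays with 526-mel medium lay beyond all 3 control arrays in each of the 12 genes, as they did for 9.53% of all genes, where chance gives 10%.

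Of the lists, 3 were shifted upward and 1 downward with 526-mel medium. Among the neurotrophic factors (adjusted p = 0.00231), LIF stood at 0.35 ± 0.11, FGF2 at 0.28 ± 0.08, FGF7 at 0.29 and EREG at 0.27; 0 of 18 passed over all genes and 4 adjusted over the list alone. The adjusted p with an estimated correlation was 0.209. The retinoid and steroid response list (adjusted p = 0.0111; with an estimated correlation, adjusted p = 0.578) held the 2 rising genes CYP1B1 and TIPARP, which were also the 2 that passed adjusted over the list alone. Without these 2 genes its adjusted p was 0.419, and without its retinoid genes 0.0499. The TGF-beta targets were shifted upward (adjusted p = 0.0111; with an estimated correlation, adjusted p = 0.578), with 0 of 18 members past either adjustment and ID1 at 0.20, ID3 at 0.22 and INHBA at 0.24. The interferon response list was shifted downward (adjusted p = 0.0499; with an estimated correlation, adjusted p = 0.578), with 17 of 23 members at a negative log2 change, IFIT1 at -0.35 and BST2, against the trend, at 0.29. Of 23 interferon genes, 0 passed over all genes, and adjusted over the list alone 1 rose and 1 fell.

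At an unadjusted p under 0.05 stood 468 genes in this comparison. METTL5 did not pass with quantile normalization (0.0507), the mean of all probe sets (0.0916), array weights (0.0976) or only the groups compared (0.106). It did not pass without control replicate 1 (0.225) or 3 (0.489), 526-mel replicate 1 (0.112), 2 (0.188) or 3 (0.197), or 397-mel replicate 1 (0.0553), 2 (0.0609) or 3 (0.0677) either. Without control replicate 1 the count was 7, and besides METTL5 IL24, LYPD1, MMP1, TIPARP and TMEM156 no longer passed, at adjusted p between 0.0559 and 0.0757. EGR1 did not pass without control replicate 3 (adjusted p = 0.151) or 526-mel replicate 2 (0.0909), IL24 without 526-mel replicate 3 (0.0548), TMEM156 without 526-mel replicate 1 (0.108), and CYP1B1 with the intensity trend and robust hyperparameters (0.278). Without 526-mel replicate 3 the TGF-beta list had an adjusted p of 0.161 and the retinoid and steroid list 0.119, and the latter had 0.15 without control replicate 2. The interferon list reached 0.56 without 526-mel replicate 2, 0.167 without control replicate 3, 0.0576 without control replicate 2, 0.054 without 397-mel replicate 3 and 0.0505 without 397-mel replicate 1. It also missed the threshold with the replicate number as a block (0.0579), with median centring (0.0578) and with only the groups compared (0.0535).

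With medium of 397-mel cells 6 genes rose and 5 fell. DHRS3, a retinaldehyde reductase induced by retinoic acid, rose by 0.63 ± 0.12 (adjusted p = 0.0243), the metalloprotease PAPPA by 0.54 ± 0.11 (adjusted p = 0.0478) and LIF, a cytokine of the IL-6 family, by 0.52 ± 0.11 (adjusted p = 0.0478). CRISPLD2, a secreted protein, rose by 0.51 ± 0.10 (adjusted p = 0.0243), STC2 by 0.49 ± 0.09 (adjusted p = 0.0206) and GPRC5A, a receptor induced by retinoic acid, by 0.44 ± 0.09 (adjusted p = 0.0478). CNIH3, an accessory subunit of AMPA receptors, fell by 0.46 ± 0.08 (adjusted p = 0.0206). The transcription factor SOX18 fell by 0.42 ± 0.09, the fatty acid binding protein FABP4 by 0.40 ± 0.08 and the interferon-induced exonuclease ISG20 by 0.40 ± 0.08, each with adjusted p = 0.0478. RPL23AP53 fell by 0.47 ± 0.08 (adjusted p = 0.0206); as a pseudogene of a ribosomal protein gene it can share probes with its relatives, so its identity is uncertain.

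The retinoid and steroid response list was shifted upward with 397-mel medium (adjusted p = 2.316e-06; with an estimated correlation, adjusted p = 0.277). DHRS3 was the 1 of 17 members that rose, and 5 passed adjusted over the list alone, among them CYP1B1 at 0.60 ± 0.13, RARB at 0.31 ± 0.08 and CYP26A1 at 0.31 ± 0.10. Its adjusted p was 0.000638 without CYP1B1 and TIPARP and 0.00883 without its retinoid genes. The TGF-beta targets were shifted upward (adjusted p = 0.000765; with an estimated correlation, adjusted p = 0.536), with 0 of 18 members past either adjustment. The DNA replication genes were shifted downward (adjusted p = 0.00872; with an estimated correlation, adjusted p = 0.776), with 17 of 18 members at a negative log2 change, MCM4 at -0.17, TYMS as the exception at 0.13 and 0 past either adjustment. The neuron markers were shifted downward (adjusted p = 0.0126; with an estimated correlation, adjusted p = 0.277): 0 of 10 passed over all genes and 1 adjusted over the list alone, the neurofilament NEFL at -0.48 ± 0.11.

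With 397-mel medium 669 genes stood at an unadjusted p under 0.05. All 3 arrays lay beyond all 3 control arrays in each of the 11 genes, as they did for 11.41% of all genes. The count was 0 without control replicate 2, 397-mel replicate 2 or 397-mel replicate 3, 2 without control replicate 1, 5 without 526-mel replicate 1 or 2, 6 without 624-mel replicate 1 and 7 without 624-mel replicate 3. It was also 0 when the 6 arrays compared were fitted alone. With the mean of all probe sets of a gene it was 3: DHRS3 and SOX18 (both 0.0844), LIF (0.0955), PAPPA (0.11), ISG20 (0.153) and CRISPLD2, FABP4 and STC2 (all 0.0587) did not pass. FABP4 also missed the threshold with the replicate number as a block (0.0503) and with array weights (0.0706). Without control replicate 3, CNIH3 and ISG20 (both 0.0745), PAPPA (0.121) and FABP4 (0.182) missed the threshold; without 397-mel replicate 1, FABP4 (0.079) and ISG20 (0.0809) did. FABP4, GPRC5A and SOX18 also missed it without 526-mel replicate 3 (all 0.0519, with LIF) or 624-mel replicate 2 (0.0623 to 0.0626, with ISG20). Without 397-mel replicate 3 the adjusted p of the TGF-beta list was 0.142 and that of the DNA replication and neuron lists 0.143; without control replicate 3 that of DNA replication was 0.186 and that of the neuron markers 0.0755, and without control replicate 2 that of DNA replication was 0.128. With the mean of all probe sets of a gene the neuron markers did not pass (0.142), at a mean of -0.0796 against -0.127.

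With medium of 624-mel cells STC2 rose by 0.57 ± 0.09 (1.483-fold, adjusted p = 0.00495) and no other gene passed. The next smallest p-values belonged to CYTIP at 0.52 ± 0.10 (adjusted p = 0.0997), TMEM156 at 0.45 ± 0.10 (0.3), EGR1 at -0.44 ± 0.10 (0.412) and the matrix protein gene MXRA5 at -0.44 ± 0.10 (0.464), which did not pass. At an unadjusted p under 0.05 stood 351 genes. STC2 did not pass without control replicate 1 (adjusted p = 0.099), control replicate 2 (0.0764) or 624-mel replicate 3 (0.0683), with log2 changes between 0.54 and 0.55; the count was 2 without control replicate 3 or 624-mel replicate 2.

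The amino acid and ATF4 response list was shifted upward with 624-mel medium (adjusted p = 2.991e-06; with an estimated correlation, adjusted p = 0.771). Of its 18 measured members 17 had a positive log2 change, and STC2 was the 1 that rose, over all genes and adjusted over the list alone. Without STC2 the list still passed by camera (adjusted p = 0.000571). The cystine transporter SLC7A11 stood at 0.21, the serine synthesis enzyme PSAT1 at 0.20 and NUPR1 at 0.22. The mean of the list was 0.27 above control in 624-mel replicate 1 and 0.043 and 0.067 in the other 2 arrays, and the adjusted p without replicate 1 was 0.179. The hypoxia list (adjusted p = 0.0101) and the TGF-beta targets (adjusted p = 0.0357) were also shifted upward, each with adjusted p = 0.771 with an estimated correlation. STC2 was the 1 of 16 hypoxia members that rose, also adjusted over the list alone, and without it the list had an adjusted p of 0.16. Of the TGF-beta targets 0 of 18 passed either adjustment. Without 624-mel replicate 2 the adjusted p was 0.0987 for hypoxia and 0.331 for the TGF-beta targets; the latter had 0.067 without 624-mel replicate 3, 0.0745 without control replicate 1, 0.0875 without control replicate 3 and 0.202 after quantile normalization.

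Only STC2 passed in the same direction in all 3 single-medium comparisons, which share their control arrays. Independent lists of these sizes would share 8.05e-07 genes, a value that leaves out the shared controls. In 100 simulations of unchanged groups against shared controls the highest count was 0. These simulations held no changed gene. Neither value therefore tests whether a gene passing in 1 medium passes in others through the shared controls. STC2 no longer passed in all 3 comparisons, leaving a count of 0, without control replicate 1, control replicate 2, 397-mel replicate 2, 397-mel replicate 3 or 624-mel replicate 3. Across genes, which are not independent replicates, the log2 changes correlated at r = 0.368 for 526-mel and 397-mel medium, 0.515 for 526-mel and 624-mel medium and 0.342 for 397-mel and 624-mel medium. The simulations without any effect gave 0.502, 0.501 and 0.501. The covariances were 0.0041, 0.00478 and 0.00339, against 0.00437, 0.00436 and 0.00436 simulated. The simulated values ranged from 0.00405 to 0.00459, 0.00413 to 0.00461 and 0.00407 to 0.00461, so the pair of 526-mel and 624-mel medium lay above its range and that of 397-mel and 624-mel medium below. The simulations drew each gene independently, which makes these ranges narrower than for genes that vary together.

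The media were then compared with each other, where the control arrays cancel. Between 526-mel and 397-mel medium, 4 genes were higher and 3 lower with 526-mel medium. CYTIP was higher by 0.70 ± 0.10 (adjusted p = 0.000985), CLK1, a kinase of splicing factors, by 0.51 ± 0.08 (adjusted p = 0.00572), IL24 by 0.46 ± 0.09 (adjusted p = 0.0254) and NPTX1 by 0.42 ± 0.08 (adjusted p = 0.0254). EGR1 stood at -0.76 ± 0.10 (adjusted p = 0.000445), the adaptor of growth factor receptors GRB10 at -0.61 ± 0.11 (adjusted p = 0.0158) and the kinase MAP3K8 at -0.49 ± 0.10 (adjusted p = 0.0452). In each of the 7 genes the 3 arrays of one medium lay beyond those of the other, as they did for 11.99% of all genes. At an unadjusted p under 0.05 stood 875 genes. The balance was not stable: 6 of 19 genes were higher with the replicate number as a block, 5 of 15 with only the groups compared and 14 of 36 with the intensity trend. The count was 2 without 526-mel replicate 1, 526-mel replicate 3 or 397-mel replicate 2, 3 without 397-mel replicate 3 and 11 without 624-mel replicate 3. CYTIP and EGR1 passed in each of these fits. NPTX1 missed the threshold without 397-mel replicate 1 (0.0726) and MAP3K8 without 526-mel replicate 2 (0.143). MAP3K8 also missed it with quantile normalization (0.102), the mean of all probe sets (0.0945, with GRB10 at 0.0544) and array weights (0.0502, with IL24 at 0.0734 and NPTX1 at 0.0716), and NPTX1 with only the groups compared (0.0567).

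The MAPK and immediate early genes were shifted downward with 526-mel against 397-mel medium (adjusted p = 0.00898; with an estimated correlation, adjusted p = 0.513). EGR1 was the 1 of 19 measured members that passed, and 5 passed adjusted over the list alone, among them FOS at -0.35, DUSP1 at -0.27 and DUSP5 at -0.24. The heat shock genes were shifted upward (adjusted p = 0.0253; with an estimated correlation, adjusted p = 0.513), with 9 of 10 members at a positive difference, DNAJB1 at 0.24, SERPINH1 at 0.21 and HSPB8 as the exception at -0.15, and 0 past either adjustment; fry, which tests whether they move one way, gave an adjusted p of 0.00462. Cell cycle genes (adjusted p = 0.00898; with an estimated correlation, adjusted p = 0.595) and DNA replication genes (0.0132; with an estimated correlation, adjusted p = 0.829) were shifted upward. Of the cell cycle genes 16 of 17 had a positive difference, with BUB1 at 0.21 and CDK1 at 0.19, and of the replication genes 17 of 18, with MCM4 at 0.20; 0 members passed either adjustment in either list. All 4 lists missed the threshold without 526-mel replicate 2 and without 397-mel replicate 2, where their adjusted p lay at 0.0653 to 0.0803 and at 0.053. DNA replication also missed it without 526-mel replicate 1 (0.146) and 397-mel replicate 3 (0.14), heat shock without 526-mel replicate 1 (0.0728) and 397-mel replicate 1 (0.0744) and with only the groups compared (0.0509), and the MAPK list without 397-mel replicate 3 (0.0609).

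Between 397-mel and 624-mel medium, 2 genes were higher and 2 lower with 397-mel medium. EGR1 was higher by 0.64 ± 0.10 (adjusted p = 0.00433) and the growth factor FGF16 by 0.47 ± 0.09 (adjusted p = 0.0236), while CNIH3 stood at -0.51 ± 0.08 (adjusted p = 0.00433) and the pseudogene RPL23AP53, of uncertain identity, at -0.49 ± 0.08 (adjusted p = 0.00866). MGP, a matrix protein that inhibits calcification, had the next smallest p at 0.58 ± 0.12 (adjusted p = 0.0558) and did not pass. At an unadjusted p under 0.05 stood 811 genes. The count was 1 without 624-mel replicate 2, 2 without 397-mel replicate 2 or 624-mel replicate 1, 7 without control replicate 3, 8 without 397-mel replicate 1 and 10 without 526-mel replicate 3. EGR1 missed the threshold without 624-mel replicate 1 (adjusted p = 0.0727) and CNIH3 without 624-mel replicate 2 (0.0554). FGF16 missed it without 397-mel replicate 3 as well (0.146) and with only the groups compared (0.0597), and EGR1 with the mean of all probe sets (0.0523, at 0.52).

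In the same comparison, the retinoid and steroid response list was higher with 397-mel medium (adjusted p = 0.000517; with an estimated correlation, adjusted p = 0.555). DHRS3 stood at 0.58 and CYP26A1 at 0.28; 0 of 17 members passed over all genes and 5 adjusted over the list alone. The MAPK and immediate early genes were higher as well (adjusted p = 0.0448; with an estimated correlation, adjusted p = 0.666), with EGR1 as the 1 of 19 that passed and 4 adjusted over the list alone. The amino acid and ATF4 list was lower with 397-mel medium (adjusted p = 0.000331; with an estimated correlation, adjusted p = 0.558), with NUPR1 at -0.43 and ASNS at -0.21, 0 members past the threshold over all genes and 1 adjusted over the list alone. Without 624-mel replicate 1 its adjusted p was 0.207. The heat shock genes were lower with 397-mel medium (adjusted p = 0.0436; with an estimated correlation, adjusted p = 0.555; fry adjusted p = 0.00977), with 9 of 10 at a negative difference and 0 past either adjustment. The heat shock list missed the threshold without 397-mel replicate 1 (0.0781) or 2 (0.0607) and without 624-mel replicate 1 (0.0954) or 2 (0.0699). It also missed it after quantile normalization (0.0784), without the dimmest genes (0.0632) and with only the groups compared (0.0522). The MAPK list missed it without 397-mel replicate 3 (0.204) or 2 (0.136), 624-mel replicate 1 (0.139) or 2 (0.0699), and 526-mel replicate 1 (0.0534), 2 (0.0539) or 3 (0.0668), as well as with the mean of all probe sets (0.063) and with only the groups compared (0.0642).

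Between 526-mel and 624-mel medium, limma called 0 genes, with 401 at an unadjusted p under 0.05. The smallest p-values belonged to CYP1B1 at 0.68 ± 0.13, PKP2, a desmosomal plakophilin, at -0.47 ± 0.10 and NPTX1 at 0.39 ± 0.08, each with adjusted p = 0.126, then CYTIP at 0.49 ± 0.10 (0.131) and GDPD2 at 0.38 ± 0.08 (0.164); none passed. The amino acid and ATF4 list was lower with 526-mel medium (adjusted p = 0.000279; with an estimated correlation, adjusted p = 0.906), with VLDLR at -0.30 and CHAC1 at -0.26, although STC2 stood at 0.21. Without 624-mel replicate 1 its adjusted p was 0.387. The endothelial and pericyte markers were lower with 526-mel medium (adjusted p = 0.0398; with an estimated correlation, adjusted p = 0.574), with CDH5 at -0.32 and EMCN at -0.21, and their adjusted p was 0.135 without 526-mel replicate 1, 0.091 without 526-mel replicate 2, 0.076, 0.0998 and 0.0722 without 624-mel replicate 1, 2 and 3, and 0.0878 without the dimmest genes. In both lists 0 members passed over all genes or adjusted over the list alone. The count of genes was 1 without 526-mel replicate 2 or 624-mel replicate 2.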

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

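The tests of scaling, single arrays, immediate early genes and the amino acid list were chosen after the results were seen; the counts over other groupings of the arrays were planned. Each gene below passed a direct test of 2 media. Each list passed camera with the preset correlation and not with an estimated correlation. Between 526-mel and 397-mel medium the log2 differences were 0.51 for CLK1, 0.70 for CYTIP, -0.76 for EGR1, -0.61 for GRB10, 0.46 for IL24, -0.49 for MAP3K8 and 0.42 for NPTX1. Between 397-mel and 624-mel medium they were -0.51 for CNIH3, 0.64 for EGR1, 0.47 for FGF16 and -0.49 for RPL23AP53. Mean list differences were 0.103 for the cell cycle, 0.0934 for DNA replication, 0.108 for heat shock and -0.107 for the MAPK genes between 526-mel and 397-mel medium (with an estimated correlation, adjusted p = 0.595, 0.829, 0.513 and 0.513). They were -0.105 for the amino acid and ATF4 list and -0.071 for the endothelial and pericyte markers between 526-mel and 624-mel medium (with an estimated correlation, adjusted p = 0.906 and 0.574). Between 397-mel and 624-mel medium they were -0.132 for the amino acid and ATF4 list, -0.0973 for heat shock, 0.0895 for the MAPK genes and 0.141 for the retinoid and steroid list (with an estimated correlation, adjusted p = 0.558, 0.555, 0.666 and 0.555). With fry, only the heat shock list passed in these comparisons, at adjusted p = 0.00462 and 0.00977. Among probe sets without a single gene name, which the gene counts leave out, 2 passed with 526-mel medium, 2 with 397-mel medium and 1 in the mean of the 3 media, and between media 5 (526-mel against 397-mel) and 2 (397-mel against 624-mel); they are not analysed further here.

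9 genes rose in the mean of the 3 media. Among 100 groupings of the 12 arrays into 4 groups of 3, the real one included, 2 gave at least 9 genes, a share under 0.05. The highest other count, 38, came when control, 397-mel and 624-mel replicates 3 took the controls' place. This points to a structure among these arrays that the media do not follow, so the share does not exclude chance. Only 3 arrays can take the controls' place, so the absence of 526-mel replicate 3 does not show whether it shares this structure. Arrays numbered 3 differed from the others in 0 genes after adjustment, and at an unadjusted p under 0.05 in 802, against 452.6 expected by chance. Those numbered 1 differed in 8 genes after adjustment. With the replicate number as a block the count was 8, without TFPI2 (adjusted p = 0.0531). Without each control array in turn the median log2 change of the 9 genes was at least 0.431, against 0.445 with all. These genes were chosen for passing with all 3 control arrays, so this cannot exclude an out-of-place control array. The count was 5, 3 and 4 without control replicate 1, 2 and 3. With either further scaling at least 8 of the 9 genes passed, and MMP1 did not after quantile normalization (adjusted p = 0.281). These genes were chosen for passing with the deposited values, which RMA had already normalized between arrays. The scalings thus show little dependence on differences left after RMA, and do not exclude an effect of that first normalization. An effect of the media stays open as a hypothesis.

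EGR1 was lower with 526-mel than with 397-mel medium. A single array does not account for it, because the highest adjusted p without each array in turn was 0.0175. Further scaling of the RMA values did not remove it (adjusted p at most 0.000762), which leaves the first normalization untested. A shift of all immediate early genes at harvest may contribute: 7 others, FOS, FOSB, IER2, DUSP1, ATF3, NR4A1 and EGR3, had a mean difference of -0.149 and moved together by fry (adjusted p = 0.000355 over the 3 gene sets tested this way), with FOS at -0.35 but FOSB at 0.11. Of these 7, FOS, FOSB, IER2, DUSP1 and EGR3 belong to the MAPK list already called downward in this comparison. The set was chosen after that result, so the fry value is not separate evidence for a shared shift. The bound set for such a shift was -0.19, a share of 0.25 of the EGR1 difference, and 2 SE over the genes reached -0.27. Handling and medium cannot be told apart here, since each group holds 1 medium and the labels give no order of collection.

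The amino acid and ATF4 list was higher with 624-mel medium by camera with the preset correlation, but not with an estimated correlation (adjusted p = 0.771) or fry (adjusted p = 0.721). The shift may rest on 624-mel replicate 1, since without it the adjusted p was 0.179. That array was not generally deviant: the SD of its deviation from its group mean over all genes was 0.0878, below the median of 0.0939 for the 12 arrays. All 3 of the 624-mel arrays had a list mean above every control array, so a shortage of amino acids in this medium stays open and cannot be told apart from a difference between single cultures.

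For the single-medium counts the 10 splits of 6 arrays are too few for a share under 0.05. The real and the highest other counts were 12 and 0 for 526-mel, 11 and 1 for 397-mel and 1 and 0 for 624-mel medium against control. They were 7 and 1 for 526-mel against 397-mel, 0 and 0 for 526-mel against 624-mel, where 10 of 10 splits gave at least 0, and 4 and 15 for 397-mel against 624-mel medium, where 2 splits gave at least 4. The 15 genes came from exchanging 397-mel replicate 3 with 624-mel replicate 1, a structure of the arrays that the media do not follow; the blocked count there was 9. Of the groupings of all 12 arrays, 22 of 100 gave at least the 4 called lists (highest other 9), so chance is not excluded for that count. For genes shared by all 3 media, 3 of 100 gave at least 1 (highest other 3), a share under 0.05. Groupings that ignore the media also reached this count, so chance is not excluded for it either.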

How the results depend on the processing

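The alternatives for lists in single-medium and between-media comparisons, and those without single members, were chosen after seeing the data. Over the named genes, 0 calls reversed in any alternative. Leaving out each array in turn gave 7 to 14 genes for 526-mel (12 in the report), 0 to 13 for 397-mel (11), 0 to 2 for 624-mel (1) and 3 to 10 for the mean of the 3 media (9). It gave 2 to 11 between 526-mel and 397-mel (7), 0 to 1 between 526-mel and 624-mel (0), 1 to 10 between 397-mel and 624-mel medium (4), 1 to 6 lists (4) and 0 to 1 genes shared by all 3 media (1). In the same order of comparisons, the intensity trend with robust hyperparameters gave 22, 31, 6, 17, 36, 3 and 33 genes, and 2 shared. Leaving out the dimmest genes (a share of 0.333) gave 17 for 397-mel, 2 for 624-mel, 13, 4 and 14 between media, and 8 lists; fewer genes are tested there. The mean of all probe sets gave 3 for 397-mel and 0 shared. Every probe set by itself gave 2 for 624-mel, 19 between 526-mel and 397-mel and 9 between 397-mel and 624-mel. Array weights gave 2 for 624-mel, 1 between 526-mel and 624-mel and 27 between 397-mel and 624-mel. Only the groups compared gave 0 for 397-mel, 2 for the mean, 15 between 526-mel and 397-mel and 0 shared. Median centring gave 11 between 526-mel and 397-mel, 5 of them higher with 526-mel, and 9 between 397-mel and 624-mel. For the mean of the 3 media, 0 lists passed with camera's estimated correlation and 0 with fry. The causes were not tested, except where fewer genes or arrays entered.

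With the replicate number as a block the counts were 13, 12, 1 and 8 against control and 19, 0 and 9 between media. The numbers were not taken to pair the arrays. Arrays with the same number correlated in their deviations at a median r of 0.0683 (2 of 18 pairs over 0.1). For arrays with different numbers the median r was -0.0279 (7 of 36 pairs over 0.1), and 4 of 12 arrays correlated best with their own number. Arrays numbered 3 differed from the others at an unadjusted p under 0.05 in 802 genes and after adjustment in 0. Those numbered 1 differed in 662 and 8, and those numbered 2 in 287 and 0, where chance gives 452.6 at the unadjusted threshold. By the threshold used here, arrays numbered 1 thus carried a signal of the replicate number in 8 genes, and the main fits held no block for it. Signal over background is not known, as no detection calls were used here.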

Other observations

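The test of the aryl hydrocarbon receptor was chosen after the results were seen. In every group, genes of fibroblast matrix had high probe set levels. In control medium the log2 level of COL1A2 was 14.08, COL3A1 12.68, COL1A1 12.26, DCN 10.93 and PDGFRA 10.15, while S100B stood at 3.32, ERBB3 at 3.89, NGFR at 4.15 and SOX10 at 5.08. Of the other Schwann cell genes named above, GAP43 stood at 4.60 and GFAP at 5.06, but MBP at 9.07 and JUN at 11.03. Levels of different probe sets are not comparable as amounts, and no detection calls were used, so these values do not give the share of any cell type. The purity of the cultures was not tested here and stays in question. The melanoma genes PMEL, MLANA and TYRP1 stood at 4.83, 4.27 and 2.97 in control medium and at 4.82, 4.27 and 2.89 with 526-mel medium.

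Inflammatory lists stayed below the threshold in the mean of the 3 media. The adjusted p was 0.941 for chemokines (15 measured), 0.136 for cytokines and receptors (23), 0.462 for NF-kB targets (16), 0.132 for the interferon response (23) and 0.976 for antigen presentation (12). Collagens (0.494), matrix glycoproteins (0.49) and glycolysis (0.678) were not called either, and NRF2 targets stood at 0.0503, with 11 of 14 members at a positive log2 change.

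Hypothesis: activity of the aryl hydrocarbon receptor may underlie the rise of CYP1B1 and TIPARP with 526-mel medium. If so, its other targets should be higher. Over 8 of them, CYP1A1, NQO1, ALDH3A1, CYP1A2, NFE2L2, XDH, SLC7A5 and ABCG2, the mean log2 change was 0.0107, with NQO1 at 0.23 and CYP1A1 at 0.05, and 2 SE over the genes reached 0.0885 (fry adjusted p = 0.559). By the bound of 0.1 first set, this would exclude the hypothesis. Several targets lie near the low end of the scale, CYP1A1 at a mean level of 4.10, so a restriction to the 4 targets above the median level of all genes was added after that result was seen. Their mean was 0.0703 and 2 SE reached 0.178, above the bound (fry adjusted p = 0.113). The outcome thus hangs on a choice made late, and the hypothesis is left undecided.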
